A study of Oryza sativa Japonica Group with 2 samples.

How the data were processed

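Small RNA was sequenced from pooled leaf segments of WT and Osaba1-1 rice, 1 library each. Per the labels' protocols, RNA of 18 to 30 nt was cut from a gel, ligated to adapters, reverse transcribed, amplified with 15 PCR cycles and sequenced on an Illumina instrument. The nature of the Osaba1-1 allele, the adapter trimmer, quality filter, aligner and genome build are not given in the sources used here. The deposited tables list each distinct sequence with its length and its read count, and these counts are raw, not normalized. The lengths run from 18 to 44 nt, wider than the gel window in the labels. Libraries were grouped by the genotype in the labels.

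From the counts, reads per 1000000 reads of 18 to 30 nt (RPM) were computed, and a zero count was taken to allow 3 reads (0.335 RPM in WT and 0.331 RPM in Osaba1-1). No genome sequence was used. The names of OsABA1 come from a gene table of assembly ASM3414082v1, none of whose coordinates are used. miRNAs were identified only as reads identical to a list of 98 mature sequences in 37 families, written by hand before the data were examined and not checked against a miRNA database, precursors or a genome, so a family could be incomplete. The list also holds tasiR-ARF, a siRNA family, which is counted among the 37 families. Of the 98 sequences, 70 were read at least once. Counts were summed per family, and families with at least 50 reads over both libraries were compared. Ratios of Osaba1-1 over WT have exact 95% intervals (Clopper-Pearson on the share of the summed reads) that cover counting error only. A family was called higher or lower where the ratio was at least 1.5-fold and the interval left out 1. Family lists were fixed before the data were examined, and each list's median was set against 10000 random lists drawn from the 8 families nearest in abundance to each member. The member itself and other members of its list could be drawn. A percentile thus places a list within the families compared and is not a comparison with independent lists.

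Choices made after the data were seen, because no genome came with them, were the comparison of single 21 nt and 24 nt sequences, the tRNA-like class and the shifted forms. Sequences with at least 100 reads over both libraries were compared at a 2-fold rule. Those that share a run of 10 nt with a listed miRNA were left out, a limit set after a first list of top sequences had held miRNA variants. tRNA-like reads, all of at least 20 nt, carry U at position 8, R at 9, G at 10, Y at 11 and A at 14. They also carry a GG between 16 and 20. These residues are conserved in tRNAs, but not every tRNA fragment has all of them at these positions. The class can thus miss tRNA fragments, which then count among the other reads. Shuffled sequences gave the chance rate. Starts of 15 nt with at least 1000 reads were compared. For the length trend, starts with at least 5000 reads and at least 10 lengths of at least 30 reads were used. Shifted forms are reads that hold nt 4 to 18 of a listed sequence.

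Families named are the 8 highest and 8 lowest ratios whose interval leaves out 1 and the 6 most abundant, with each family under 50 reads named once. For the 21 nt and 24 nt sequences, 2 in each direction are named, ranked by the interval bound nearest 1. For tRNA-like starts, the 3 most abundant and the 2 highest and 2 lowest ratios are named. Alternatives were other scalings (to the listed miRNA reads, to all reads of 18 to 44 nt, the median ratio over families, and TMM from edgeR 4.0.16), 3′ isomiRs, 1 internal mismatch, other read minimums, distinct sequences and shifted forms. edgeR served only for the TMM factors, 0.940 for WT and 1.06 for Osaba1-1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used. Tested on simulated counts, 95.7% of intervals of the 29 families held the true ratio. In the simulated 21 nt comparison of 1189 sequences, 100 of 100 sequences changed 4-fold and 99 of 100 changed 3-fold were called and 0 unchanged ones were. In the 24 nt comparison of 2540 sequences, the calls were 100 of 100, 100 of 100 and 0. The rule for a falling length trend counted 54% of 100 simulated starts with no trend and 100% of 100 with a falling trend. The simulated counts hold counting error alone, so these rates leave out variation between plants.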

Results

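Small RNAs were sequenced from rice leaves of the cultivar Nipponbare, with 1 library from wild-type plants (WT) and 1 from plants labelled Osaba1-1. The mutant is named for OsABA1, whose product is zeaxanthin epoxidase, an enzyme on the route to the hormone abscisic acid (ABA), and the comparison asks which small RNAs differ in leaves of that mutant. Leaf segments of 40-day-old plants lay within 2 cm of a cut made 4 cm from the tip of the fifth or the sixth leaf, and each library pooled at least 15 seedlings. The WT library held 11548188 reads of 18 to 44 nt and the Osaba1-1 library 10379446, of which 8947685 and 9067780 were 18 to 30 nt long. The reads fell into 1974035 distinct sequences in WT and 2080932 in Osaba1-1, and 77.6% and 78.0% of these were read a single time. With 1 library per genotype, no difference below has a replicate check and no p-value was computed. The 95% intervals of shares and ratios are exact (Clopper-Pearson), and those of list medians come from Poisson redraws of the counts. They cover counting error only. Amplified reads are not independent molecules, so the intervals can be too narrow even for that. Reads from the OsABA1 locus were not analysed here, because no genome sequence was used, so the genotype labels were not checked.

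The most frequent single lengths in both libraries were 21 nt and 24 nt, the size classes usual for plant leaves. The 21 nt class holds most miRNAs and the 24 nt class holds most heterochromatic small interfering RNAs (siRNAs). The 21 nt reads made up 21.9% of WT reads (95% interval 21.88 to 21.93%) and 23.3% of Osaba1-1 reads (23.23 to 23.28%). The 24 nt reads made up 21.7% in WT and 25.8% in Osaba1-1, so that the ratio of 24 nt to 21 nt reads was 0.990 in WT and 1.11 in Osaba1-1. The difference in share was widest for reads of 31 to 44 nt, which took 22.5% of WT reads and 12.6% of Osaba1-1 reads (ratio 0.561, interval 0.560 to 0.562). Reads of 18 to 19 nt went the other way, with 2.05% in WT and 4.12% in Osaba1-1 (ratio 2.01, interval 2.00 to 2.02). Among distinct sequences the 24 nt class took 60.2% in WT and 61.0% in Osaba1-1. Because the libraries differed so much outside the labelled 18 to 30 nt window, read levels below are reads per 1000000 reads of 18 to 30 nt (RPM), where 21 nt reads were 28.3% in WT and 26.6% in Osaba1-1 and 24 nt reads 28.0% and 29.5%.

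**Figure D1:**
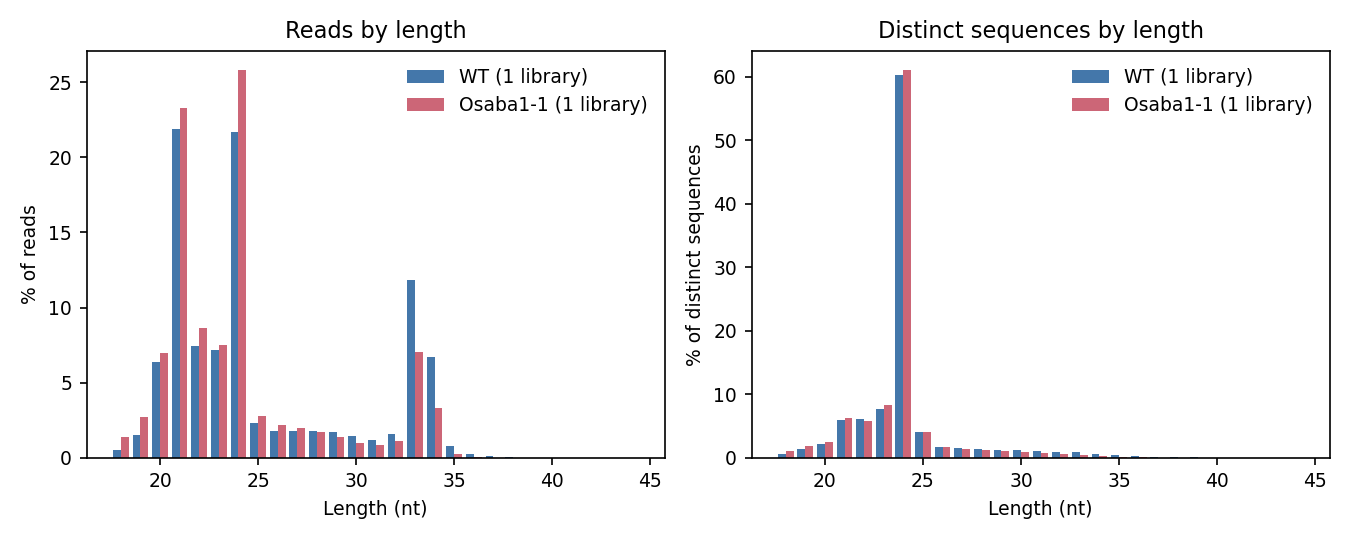
Share of reads (left, % of reads of 18 to 44 nt) and of distinct sequences (right, %) at each length in nt, with a bar per library for WT and Osaba1-1. Reads peak at 21, 24 and 33 nt, and the 33 nt peak is 11.8% in WT and 7.04% in Osaba1-1, while the 24 nt class leads among distinct sequences in both.

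The first nucleotide, which in plants goes with the Argonaute protein that a small RNA is loaded into, had the usual pattern in both libraries. Uridine opened 84.1% of 21 nt reads in WT and 79.8% in Osaba1-1, and adenosine opened 59.1% and 58.2% of 24 nt reads. The 21 nt preference was weaker without reads identical to a listed miRNA, where uridine opened 68.4% of 21 nt reads in WT and 59.2% in Osaba1-1. An unlisted 21 nt miR156 form that opens with uridine was still counted there, with 545219 reads in WT and 365738 in Osaba1-1. The 68.4% and 59.2% are therefore not shares of reads outside miRNAs. Among distinct 21 nt sequences the uridine shares were 43.4% and 40.3%.

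The clearest difference among miRNAs was a higher level in Osaba1-1 of families known to respond to copper supply. miR398, which targets copper/zinc superoxide dismutases, was read 9 times in WT and 81 times in Osaba1-1, a ratio of 8.88 (interval 4.45 to 20.1). miR408, which targets plantacyanin-type copper proteins, rested on more reads, with 121 RPM in WT and 872 RPM in Osaba1-1 (ratio 7.23, interval 6.78 to 7.71). Most of these reads were the other arm of its precursor, CAGGGATGAGGCAGAGCATGG, with 993 and 7250 reads, and the targeting strand CTGCACTGCCTCTTCCCTGGC had 87 and 659 reads (ratio 7.47, interval 5.97 to 9.46). miR528, a monocot family that targets copper-binding oxidases, had 5128 RPM in WT and 21896 RPM in Osaba1-1 (ratio 4.27, interval 4.23 to 4.31), from 45886 and 198544 reads. For miR397, which targets laccases, the listed mature sequences were read 55 and 58 times (ratio 1.04, interval 0.707 to 1.53). Most reads of miR397 type had other ends, however, and forms that share nt 4 to 18 of a listed sequence numbered 4323 in WT and 16730 in Osaba1-1 (ratio 3.82, interval 3.69 to 3.95).

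Of the 37 families in a list written before the data were examined, 29 had at least 50 reads over both libraries. Among these, 8 were at least 1.5-fold higher in Osaba1-1 with an interval above 1, 3 were at least 1.5-fold lower with an interval below 1, and 18 did neither. Besides miR398, miR408 and miR528, the higher families were miR160, miR169, miR390, miR164 and miR1850. miR160, which targets auxin response factors, had a ratio of 3.22 (interval 1.90 to 5.70) from 19 and 62 reads. miR169, which targets NF-YA transcription factors, had 44.9 RPM in WT and 105 RPM in Osaba1-1 (ratio 2.34, interval 2.08 to 2.64). miR390, the trigger of TAS3 siRNAs, had a ratio of 1.83 (interval 1.498 to 2.245), and miR164, which targets NAC genes, a ratio of 1.62 (interval 1.56 to 1.67) at 641 and 1035 RPM. The ratio of miR1850 was 1.56 (interval 1.45 to 1.69). Median-ratio and TMM scaling ended the calls of miR164 (log2 ratios 0.48 and 0.51) and miR1850 (log2 ratios 0.43 and 0.47).

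The lower families were miR1432, miR162 and miR167. miR1432 was 2.09-fold lower in Osaba1-1 (interval 1.72 to 2.56; 312 and 151 reads). miR162, which targets DCL1, was 1.62-fold lower (interval 1.42 to 1.86), and miR167, which targets auxin response factors, 1.58-fold lower (interval 1.56 to 1.59) at 13006 and 8247 RPM. The miR167 call was lost with reads of up to 2 nt more or less at the 3′ end counted (ratio 0.917), with shifted forms (ratio 0.914), and with scaling to listed miRNA reads (log2 ratio -0.53) or to all reads of 18 to 44 nt (log2 ratio -0.48). Those 2 scalings also ended the miR162 call (log2 ratios -0.58 and -0.53). Of the other families among the 6 most abundant, miR168, which targets AGO1, had 103495 RPM in WT and 89936 RPM in Osaba1-1 (ratio 0.869), and miR156, which targets SPL genes, 47401 and 36433 RPM (ratio 0.769). miR166, which targets HD-ZIP III genes, had 17078 and 12712 RPM (ratio 0.744), and miR535 1096 and 895 RPM (ratio 0.816). miR159, a less abundant family, had 77.2 and 56.4 RPM (ratio 0.730, interval 0.650 to 0.819).

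The numbers of higher and lower families depended on the scaling of the libraries. The median log2 ratio over the 29 families was 0.21 in RPM, and scaling by that median gave 6 higher and 6 lower families. TMM scaling gave 6 and 5, and scaling to the listed miRNA reads gave 11 and 1 and scaling to all reads of 18 to 44 nt 12 and 1. The 8 higher families were all among the 11 and among the 12. The listed sequences of miR319, miR395, miR530, miR437, miR2118 and miR2275 were read 0 times, which allows these sequences up to 0.335 RPM in WT and 0.331 RPM in Osaba1-1. Shifted forms of miR395 were read 13 times in WT and 25 times in Osaba1-1, those of miR437 6 and 4 times, those of miR530 2 and 3 times, those of miR319 0 and 2 times and those of miR2275 1 and 0 times. miR394 with 4 reads and miR529 with 43 reads over both libraries were not compared.

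**Figure D2:**
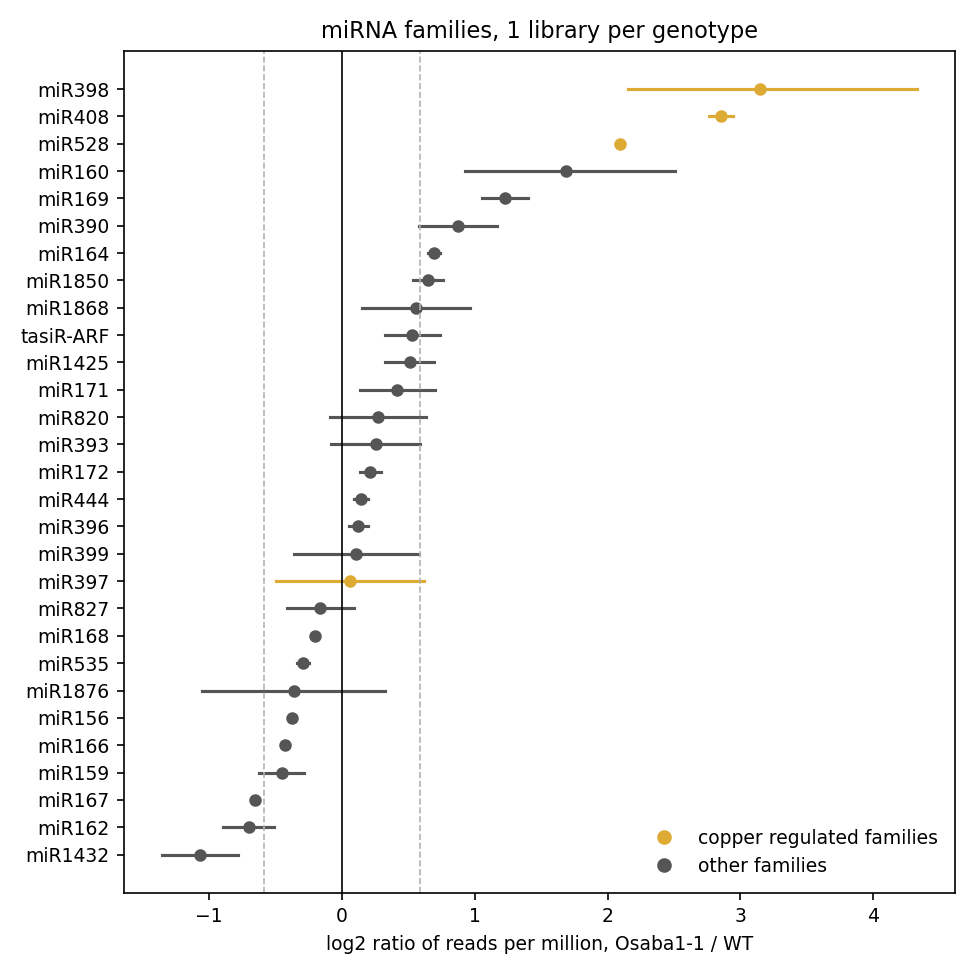
Log2 ratio of RPM (Osaba1-1 over WT) of the 29 families compared, which are miRNAs and tasiR-ARF. Each is a point with its exact 95% counting interval as a line. Dashed lines mark a 1.5-fold difference and gold marks the copper list. miR398, miR408 and miR528 stand at the top and miR1432 at the bottom, and a shift of all points by 0.21 would set their median to 0.

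By the lists fixed before the data were examined, the copper families stood apart from the rest. Their median log2 ratio was 2.47 (counting interval 2.19 to 2.52), at percentile 99.62 among 10000 random lists of as many families with like abundance, and 3 of the 4 members were higher. With shifted forms counted, 4 of 4 were higher. The random lists could draw members of the list itself, so the percentiles here place each list within the same families compared. Of the 9 auxin and leaf development families compared, 3 were higher (miR160, miR164 and miR390), 1 was lower (miR167) and 5 were neither, with a median of 0.42 at percentile 72.8. The ABA and drought list had 7 families compared, of which miR169 and miR408 were higher and 5 were neither, with a median of 0.12 at percentile 20.04 that became -0.090 under median-ratio and -0.056 under TMM scaling. miR408 and miR397 are in both this list and the copper list. The vegetative phase list, with miR156, miR535 and miR172 (ratio 1.16, interval 1.10 to 1.23) as its 3 compared members, had a median of -0.29 at percentile 5.23 and no member past the 1.5-fold rule. The silencing list of miR162 and miR168 had a median of -0.45 at percentile 17.1, with 1 of 2 lower. The 8 grass or rice families compared had a median of 0.39 at percentile 71.8, with miR528 and miR1850 higher and miR1432 lower. The 2 phosphate and sulphate families compared (median -0.03, percentile 23.2) and the 2 long miRNA families (median 0.10, percentile 20.2) had no member past the rule, and the listed sequences of the reproductive families were not read.

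Outside the listed miRNAs, most single sequences of 21 nt and of 24 nt did not pass a 2-fold rule. Those of 21 nt that passed were more often higher than lower in Osaba1-1. The median log2 ratio of the sequences compared was 0.20 at 21 nt and 0.10 at 24 nt. Sequences of tRNA-like reads were not left out. Of 1189 sequences of 21 nt with at least 100 reads over both libraries, 78 were at least 2-fold higher with an interval above 1, 23 were lower by the same rule and 1088 did neither. Of 2540 sequences of 24 nt, 44 were higher, 33 lower and 2463 neither. Scaling to the reads of each length gave 102 higher and 17 lower at 21 nt, and at 24 nt it turned the balance to 35 higher and 41 lower. The 21 nt sequence CAGGACAAATTTGGAGGTCGA was read 10 times in WT and 99 times in Osaba1-1 (ratio 9.77, interval 5.095 to 21.002), and CGGAGACGGCAGCTGGCCCCC 10 and 90 times (ratio 8.88, interval 4.61 to 19.1). TGCTTGGTTGGTTTGTCGGCG was read 188 times in WT and 1 time in Osaba1-1, 191-fold lower with an interval of 33.8 to 7565, and AGGCTGTGGAGAGATGGCTGA 124 and 25 times, 5.03-fold lower (interval 3.25 to 8.07). Among 24 nt sequences, AGACTAGTGGGAAAGGAGAAGGCA was read 11 and 92 times (ratio 8.25, interval 4.40 to 17.1) and ATCCTAACGAACGAACGATTTGAA 24 and 156 times (ratio 6.41, interval 4.16 to 10.3). GATAACGATATCGGGTGGCAAGAG was read 102 times in WT and 1 time in Osaba1-1, 103-fold lower with an interval of 18.1 to 4122, and AGCAAGATATTGGGTATTTCTTTT 181 and 28 times, 6.55-fold lower (interval 4.38 to 10.1). The sequences compared held 16.6% of 24 nt reads in WT and 16.1% in Osaba1-1, so most 24 nt reads were too thinly spread over sequences for this comparison, and genome positions were not analysed here.

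Reads resembling the 5′ part of a tRNA made up 23.7% of WT reads and 15.3% of Osaba1-1 reads of 18 to 44 nt, and within 18 to 30 nt 6.24% and 5.29%. They were recognised by conserved tRNA residues in reads of at least 20 nt. Among distinct sequences of at least 20 nt, 0.838% in WT and 0.674% in Osaba1-1 matched, against 0.143% of shuffled WT ones. Shorter reads, which were more frequent in Osaba1-1, thus count only in the totals. The reads that begin GGGATTGTAGTTCAA alone held 17.4% of WT reads and 10.1% of Osaba1-1 reads (ratio 0.579, interval 0.578 to 0.581). The most abundant of them, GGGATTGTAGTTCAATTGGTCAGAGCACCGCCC of 33 nt, was read 1149608 times in WT and 620463 times in Osaba1-1. Within 18 to 30 nt, where few of these reads lie, the same start was higher in Osaba1-1 (ratio 1.46, interval 1.41 to 1.52). The next most abundant starts, GGGGATGTAGCTCAG and GGAGAGATGGCTGAG, had ratios of 1.12 and 0.925, and within 18 to 30 nt of 0.995 and 1.09. GGGCTATTAGCTCAG was 5.36-fold lower in Osaba1-1 (interval 5.27 to 5.45, from 99559 and 16697 reads), and 6.01-fold lower within 18 to 30 nt. Only 2.69% and 2.10% of its reads were over 30 nt. This start thus held about all of the difference of the tRNA-like class within 18 to 30 nt (558377 and 479492 reads). GCGCTCTTAGTTCAG was 2.66-fold lower over all lengths (interval 2.52 to 2.82), but within 18 to 30 nt its ratio was 1.12. The highest ratios were 2.05 for GCGGGGATAGCTCAG (interval 1.95 to 2.15) and 1.86 for GTTGAGATGGCCGAG (interval 1.69 to 2.06), and within 18 to 30 nt 1.82 and 1.65. Single sequences of 18 nt, the length most raised in Osaba1-1 among all reads (ratio 2.78), held 325 and 1545 reads of the first start and 301 and 667 reads of the second.

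**Figure D3:**
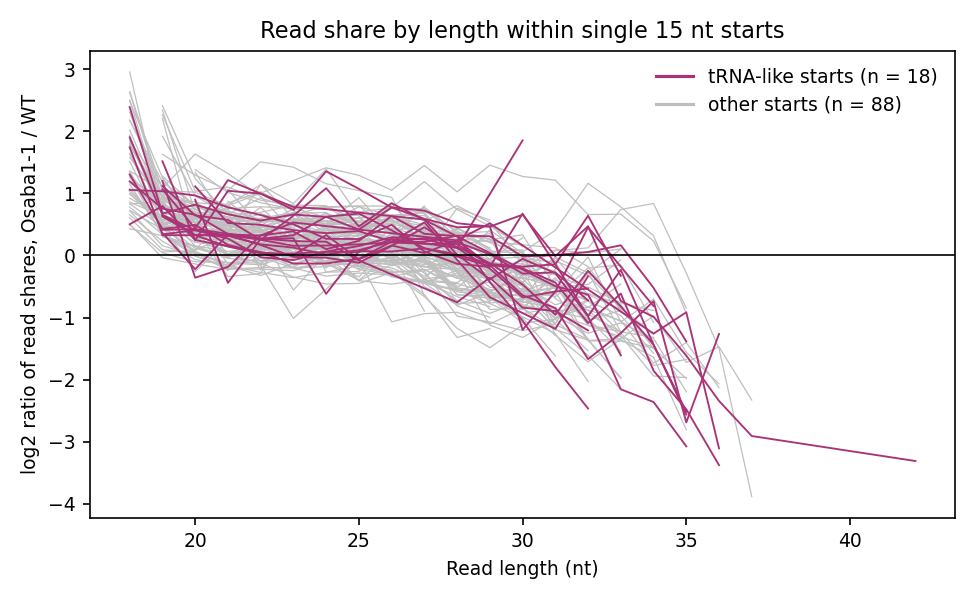
Log2 ratio of read shares (Osaba1-1 over WT) against read length in nt, with a line for each of 106 abundant 15 nt read starts, of which 18 are tRNA-like (purple) and 88 are not (grey). By slope and rank correlation 105 of the 106 lines fall, with median slopes of -0.13 and -0.13 per nt in the 2 kinds, and the exception is the tRNA-like start GGTGTCGTGGTGTAG with a slope of 0.08 per nt.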

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

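The tests of the 3 patterns below were chosen after the results were seen, and the lists of miRNAs of other organisms before the data were examined. Reads identical to a few miRNAs of other organisms lay above the limit that a count of 0 allows. Sequences of 4 dicot miRNAs were read 56 times in WT and 31 times in Osaba1-1. Sequences of 4 animal miRNAs were read 860 times in WT and 578 times in Osaba1-1.

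The lower share of long reads in Osaba1-1 went with read length in tRNA-like and other reads. Of 106 abundant 15 nt read starts, 105 (99.1%) had a log2 ratio that fell with read length by both slope and rank correlation. The median slope was -0.13 per nt, and GGTGTCGTGGTGTAG (slope 0.08) was the exception. Of simulated starts with no trend, 54% counted as falling. Many of the 106 starts overlap within the same RNA, and all come from the same pair of libraries. The simulated starts were independent, so the 54% is not a like baseline. A loss of tRNA-derived fragments alone predicts a lower ratio for tRNA-like reads than for other reads of the same length. At 31 to 36 nt the median difference in log2 ratio was 0.10 in the other direction (SD 0.37 over 6 lengths). The differences changed sign between lengths, with -0.48 at 31 nt and 0.48 at 32 nt. Other reads can also hold tRNA fragments that miss the tRNA-like rule, so this comparison cannot decide the question. A size window shifted to shorter RNA at gel purification of the Osaba1-1 library would give such a fall with length. More RNA breakage in that sample predicts the same slope and was not told apart from it. GGGCTATTAGCTCAG was not among the 106 starts and differed in level. From 26 to 31 nt its difference from all reads of the same length lay between -1.86 and -2.42 log2 units. Its own log2 ratio went from -1.56 at 26 nt to -2.87 at 31 nt.

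The copper families were higher in Osaba1-1 by more than the scaling of the libraries or the size window would give. Technical causes that act on single sequences were not tested. The lowest median log2 ratio of the copper families over the other 4 scalings was 2.26, against 2.47. Each scaling shifts every family alike, so this only sets the size of the shifts against that of the difference. The size window predicts a like rise of all 21 nt reads, whose log2 ratio in RPM was -0.087. With 1 library per genotype, genotype cannot be told apart from another difference between the plant pools, such as copper supply or leaf stage. An effect of Osaba1-1 on copper-responsive miRNAs therefore stays a hypothesis, untested here.

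Variants of the most abundant miR166 sequence at position 11, counted from its 5′ end, were far more frequent in Osaba1-1 than in WT. C11A was read 37 times in WT and 1272 times in Osaba1-1, C11G 4 and 1234 times and C11T 32 and 322 times, together 5.54 and 297 per 10000 reads. A sequencing error at that cycle would raise other abundant sequences too, but the largest excess of Osaba1-1 over WT among 19 others was 24.9 per 10000 against 292 for miR166, but by the raw rate in Osaba1-1, tried first, another sequence reached 256 (231 in WT) and the test went the other way. A single variant locus would give the same base, and the most frequent base held 44.98% of the variant reads. What gave the variants stays open, and position 15 also differed, with 7.29 in WT and 79.9 in Osaba1-1 per 10000.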

How the results depend on the processing

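No paired analysis was possible because each genotype has 1 library. Settings that need a genome (genome-matching reads, uniquely mapped reads, locus counts) were not run. Of 112 values of the 16 named families under other scalings or read matches, 97 kept their direction and side of the rule, 10 fell below it, 5 passed it and 0 reversed. The settings with scaling to reads of 18 to 44 nt, shifted forms, reads of 18 to 30 nt only, scaling of 21 nt and 24 nt sequences to reads of their length and 30 reads as the minimum were chosen after seeing the data, as were TMM and 1 internal mismatch for the list medians, and where no construction is named the cause was not tested.

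Counting each distinct sequence once changes what is counted, and gave 6.01% (WT) and 6.34% (Osaba1-1) at 21 nt, 60.2% and 61.0% at 24 nt, 4.77% and 2.53% at 31 to 44 nt, 43.4% and 40.3% uridine at 21 nt, 58.3% and 57.3% adenosine at 24 nt and 0.821% and 0.653% tRNA-like. Reads of 18 to 30 nt only gave 28.3% and 26.6% at 21 nt, 28.0% and 29.5% at 24 nt and 6.24% and 5.29% tRNA-like. Without listed miRNAs, uridine opened 68.4% and 59.2% of 21 nt reads. A minimum of 500 reads left 5 higher families, from fewer families tested. The lower families numbered 1 with scaling to listed miRNA reads, 1 with scaling to reads of 18 to 44 nt, 6 under median-ratio scaling and 5 under TMM. These scalings shift every log2 ratio, by 0.12, 0.17, -0.21 and -0.18.

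Under median-ratio scaling the list medians were -0.51 (vegetative phase), 0.20 (auxin and leaf), -0.090 (ABA and drought, reversed from 0.12), -0.66 (silencing) and 0.18 (grass or rice). With scaling to listed miRNA reads they were -0.17 (vegetative phase), 2.60 (copper) and -0.33 (silencing). Under TMM they were -0.47 (vegetative phase), -0.056 (ABA and drought, reversed) and -0.63 (silencing). With scaling to reads of 18 to 44 nt they were -0.12 (vegetative phase), 0.59 (auxin and leaf), 2.65 (copper), -0.28 (silencing) and 0.56 (grass or rice). With 1 internal mismatch the vegetative phase median was -0.049. There miR529, with 56 and 143 reads, passed the minimum of 50 reads and joined the list. The log2 ratios of miR156 (-0.38) and miR535 (-0.31) stayed below 0. With shifted forms the medians were -0.040 (vegetative phase), 0.17 (auxin and leaf), 2.52 (copper) and 0.16 (grass or rice). The vegetative phase list again held miR529, with 57 and 148 reads. A minimum of 30 reads, which admits more sequences, gave 362 higher and 115 lower at 21 nt and 630 and 371 at 24 nt. Depth limits the comparison of single sequences to the few that were read often, and 61.9% of WT and 60.8% of Osaba1-1 reads of 24 nt belong to sequences read in both libraries.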

Other observations

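Members of a miRNA family differed from each other, and the members named here were chosen after their values were seen. Within miR169, which targets NF-YA genes, the miR169a sequence CAGCCAAGGATGACTTGCCGA had 1.34 RPM in WT and 18.3 RPM in Osaba1-1 (ratio 13.7, interval 7.61 to 26.95), while the most abundant member, CAGCCAAGGATGACTTGCCGG of miR169b/c, had a ratio of 1.72 (interval 1.49 to 2.00). Within miR162, the miR162b sequence TCGATAAGCCTCTGCATCCAG was 4.16-fold lower in Osaba1-1 (interval 3.01 to 5.85) and the miR162a sequence TCGATAAACCTCTGCATCCAG 1.25-fold lower (interval 1.07 to 1.45). Within miR167, the 21 nt sequence TGAAGCTGCCAGCATGATCTA was 1.69-fold lower (interval 1.68 to 1.71), the 21 nt sequence TGAAGCTGCCAGCATGATCTG had a ratio of 1.39 (interval 1.35 to 1.44), and the 22 nt form TGAAGCTGCCAGCATGATCTGA, with 396741 and 401811 reads, had a ratio of 0.999.

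Unlisted forms held many reads. The 21 nt miR156 form TTGACAGAAGAGAGTGAGCAC was read 545219 times in WT and 365738 times in Osaba1-1, 1.51-fold lower (interval 1.504 to 1.517), more reads than the listed 20 nt form in both. The leading miR397 forms were TTGAGTGCAGCGTTGATGAACC (2686 and 9315 reads, ratio 3.42, interval 3.28 to 3.57) and TTGAGTGCAGCGTTGATGAAC (1345 and 5570 reads, ratio 4.09, interval 3.85 to 4.34). The 24 nt miR820 form TCGGCCTCGTGGATGGACCAGGAG had 7305 and 6558 reads (ratio 0.886, interval 0.857 to 0.916). For tasiR-ARF, which targets auxin response factors, the listed sequences had a ratio of 1.44 (interval 1.25 to 1.67) and the shifted forms 0.880 (interval 0.835 to 0.928).

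The libraries shared 538405 of 3516562 distinct sequences, which held 85.9% of WT reads and 83.1% of Osaba1-1 reads. At 21 nt, shared sequences held 96.2% and 95.3% of reads.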
